A study of Mus musculus with 11 samples.

How the data were processed

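Total RNA from mouse lung was sequenced after ribosomal RNA depletion with a directional library kit, per the labels' protocols. The deposited values are a normalised signal, in CPM of a library size multiplied by a normalisation factor, and no raw counts were used here. The submitters' processing notes name Trimmomatic 0.38, RSEM 1.3.0, Bowtie2, edgeR and the genome build GRCm39, without roles or settings. Every deposited value was a whole multiple of its library's smallest value within 0.01, so 100% of values gave whole reads. The factors implied by the values equalled edgeR's TMM factors computed from those reads, with a largest difference of 2.22e-16.

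The file held 23255 Ensembl genes in 11 libraries. Gene names came from an annotation of an earlier build (GRCm38, GENCODE M21), used for names, transcript length and GC content only, and no coordinates are given. It named 23123 IDs and left 132 without a name. In the file 33 genes had values identical to those of another gene, so reads shared between near-identical genes remain uncertain. Libraries of a group differed by at least 3.67 times the counting variance (chi-square per degree of freedom), so none was counted as a duplicate.

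Genes with a mean of at least 1 CPM over the 11 libraries were kept (16225). Values were tested as log2(value + 1) with limma 3.58.1 (R 4.3.3), with a mean-variance trend and 3 groups in 1 fit (8 residual degrees of freedom), and Benjamini-Hochberg adjustment over all genes kept with a threshold of 0.05. Differences are on this log2(value + 1) scale, which understates the change of low genes. Fold directions are the group named first minus the other. Recovery was tested on simulated data with 200 genes changed: for naphthalene against control 37% of genes changed 2-fold and 87% changed 4-fold were called, with 8 false calls (16169 genes), for osimertinib against naphthalene 61% and 91% with 25 (16107 genes), and for osimertinib against control 42% and 91% with 4 (15529 genes). The simulated genes were independent, with 1 dispersion per gene for all libraries. Libraries that stand apart, as osimertinib 3 does here, were not simulated, so recovery in these data may differ.

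The comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Of 43 fixed lists of cell type markers and pathway members, 39 had at least 5 members among the kept genes. They were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the lists of a comparison. Lists of markers describe genes and were not used to estimate cell shares. A gene was named where it was among the 8 largest rises or falls past the threshold with groups that did not overlap and a mean of at least 5 CPM. Where fewer passed, the smallest unadjusted p filled up to 4 per direction, given as values. Up to 4 members of each called list and of 5 lists fixed in advance, and 14 anchor genes, were named too, and some genes that the rule picks are not reported here. Any other gene named was chosen after its values were seen, and is introduced as such.

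The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of 5 CPM, median-ratio rescaling, equal totals, quantile normalisation, only the groups compared, array weights, no variance trend, an added log2 change of at least 1, the replicate number as a block, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Libraries with the same replicate number were checked for pairing by the correlation, across genes, of their deviations from the group means. Between naphthalene and osimertinib all 3 correlations were over 0.1 (0.122, 0.159 and 0.523), so the numbers were taken to pair these libraries. The pairing comes from the values alone, since the labels used here do not say what a number shares, and 2 of those 6 libraries, naphthalene 3 and osimertinib 3, correlated best with their own number. Naphthalene 1 and 2 correlated best with osimertinib 4 (0.229 and 0.270), so the pairing is weakly founded. The blocked fit held all 3 groups. Numbers 4 and 5 occur in the osimertinib group only, so the blocked contrasts with osimertinib rest on osimertinib 1 to 3. After the data were seen, settings were added that took account of the libraries with a high read share and of osimertinib 3. On the recovered reads edgeR called 0, 0 and 1 genes in naphthalene against control, osimertinib against naphthalene and osimertinib against control, and DESeq2 12, 33 and 78, where DESeq2 gave no adjusted p for 5104, 1961 and 2276 genes.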

Results

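RNA was sequenced from the lungs of C57BL/6 mice in 11 libraries. There were 3 libraries from untreated control mice, 3 from mice given naphthalene, which injures the club cells of the airway, and 5 from mice given osimertinib, an inhibitor of the EGF receptor (EGFR), after naphthalene. The series concerns naive CD4+ T cells in the pneumonitis that osimertinib can bring about, so the lists of lymphocyte, club cell and EGFR pathway genes bear most directly on its question. The labels used here give no dose, time, sex or batch, and do not say what separates the replicates, so p-values measure the spread between these samples, which may be technical.

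The deposited values gave back between 5045361 and 13009975 gene reads per library. The libraries differed in what those reads covered. The gene ENSMUSG00000119584, which has no name in the annotation used here, took 52.6% (95% Wilson interval 52.6 to 52.7) of the reads in naphthalene 1, 60.3% (60.2 to 60.3) in naphthalene 2, 46.8% (46.7 to 46.8) in naphthalene 3 and 43.9% (43.8 to 43.9) in osimertinib 2. It took at most 0.0337% in each of the other libraries. The intervals cover counting error only. Outside this gene, naphthalene 1 to 3 and osimertinib 2 held 2403780, 2018541, 2686323 and 2965328 reads, and the other libraries 8418669 to 13006929. A single read was worth between 0.0568 and 0.459 in the deposited unit (CPM of TMM-normalised library size), so genes with values near 1 rest on few reads in those 4 libraries. Osimertinib 3 stood apart on the first principal component (score −72.7, with 38.4% of the variance). The unnamed gene ENSMUSG00000118841 took 16.7% of its reads (95% Wilson interval 16.7 to 16.7), against 0.836 to 4.55% in the other libraries. These shares were recorded for a pair of genes, so they may count a second gene. Log2 differences are given on the deposited scale and are not recentred on the median gene, which lay there at log2 −0.06 for naphthalene against control, 0.06 for osimertinib against naphthalene and −0.01 for osimertinib against control. With every library rescaled to the same total, the median gene lay at −1.45, 1.10 and −0.34.

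**Figure D1:**
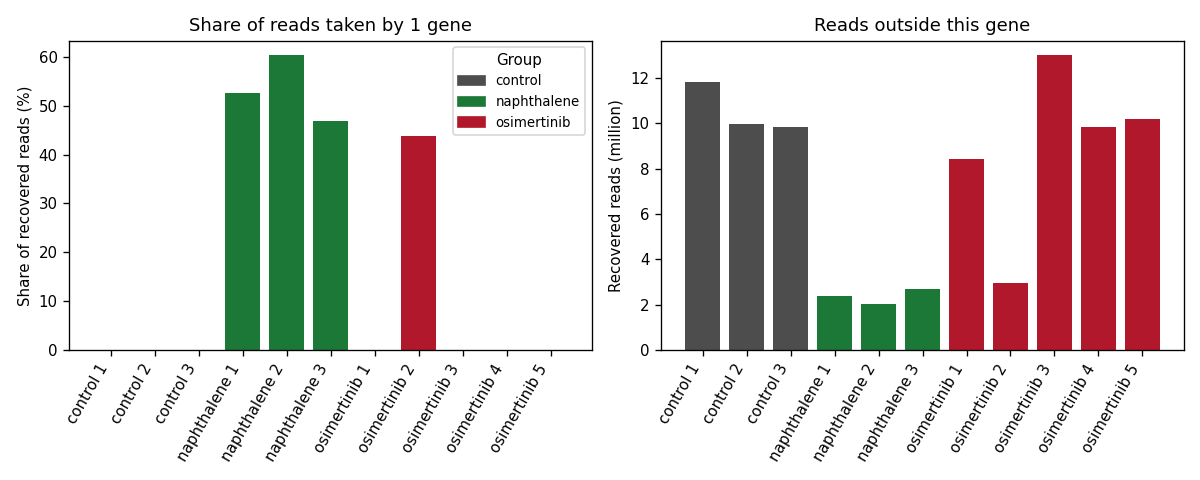
Share of recovered reads, in percent, taken by the unnamed gene ENSMUSG00000119584 (left) and recovered reads outside this gene, in units of 1e6 reads (right), with 1 bar for each of the 11 libraries, coloured by group. The share lies between 43.9 and 60.3% in naphthalene 1 to 3 and osimertinib 2 and at or below 0.0337% in the others.

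Naphthalene was set against control to ask what the injury alone left in the lung. The clearest fall was in Cldn10, a claudin of club cells, at 4.77 ± 0.56 (SD, n = 3) against 13.3 ± 1.54 (SD, n = 3) in control, a log2 difference of −1.31 (SE 0.20). It was the 1 of 16 club cell genes that fell adjusted over the list alone, a count of 2 without naphthalene 2, naphthalene 3 or osimertinib 3. That count was 0 with the high read share as a term in the fit, which only osimertinib 2 set against the other 4 osimertinib libraries can estimate, so that values with this term rest on 1 library. The secretoglobin Scgb1a1, the main secreted protein of club cells, was at 6615 ± 2339 (SD, n = 3) against 11111 ± 1306 (SD, n = 3), and Cyp2f2, the cytochrome P450 that activates naphthalene, at 844 ± 311 against 1299 ± 156; neither passed a test. No gene passed over all 16225 genes tested: limma called 0, with 1211 genes at an unadjusted p under 0.05 (280 higher, 931 lower), edgeR called 0 and DESeq2 12. The smallest adjusted p was 0.258. In 2626 genes (16.2%) the values of both groups did not overlap, where chance gives 10%.

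Of the 39 lists tested, 6 were called in this comparison, and none of the 6 calls held with an estimated correlation (adjusted p = 0.64 for the endothelial and immediate early lists and 0.823 for the other 4) or by fry. The club cell list was lower (median log2 −0.39, 13 of 16 members below 0; adjusted p = 0.823 with an estimated correlation). So were the immediate early genes (−0.51, 12 of 12 below 0; adjusted p = 0.64 with an estimated correlation), transcription factors and regulators induced within minutes of a stimulus, such as Dusp1 at 84.9 ± 31.5 against 164 ± 37.1. Smooth muscle genes were lower (−0.41; adjusted p = 0.823 with an estimated correlation), with the actin-binding protein Tagln at 29.5 ± 2.34 against 45.0 ± 11.3. So were endothelial genes (−0.20; adjusted p = 0.64 with an estimated correlation), of which the receptor Tie1 fell adjusted over the list alone (108 ± 12.3 against 145 ± 5.85). Genes of alveolar type 2 cells, which make surfactant, were higher (0.35, 14 of 14 above 0), for example Lamp3 at 571 ± 88.9 against 350 ± 18, and genes of cholesterol synthesis were higher too (0.19; adjusted p = 0.823 with an estimated correlation for both lists). In these last 2 lists and in the smooth muscle and immediate early lists 0 members passed adjusted over the list alone, and with limma 0 members of any list passed over all genes. With DESeq2 Cldn10 of the club cell list did (adjusted p = 0.00565). The 1 endothelial gene was 0 without control 1, control 2, control 3, naphthalene 1 or naphthalene 3, with median-ratio rescaling, without a variance trend and with the read-share term, and 2 to 6 in other settings. Without control 1 the counts were 5 lower immediate early and 2 lower smooth muscle genes, and without osimertinib 3 they were 4 lower endothelial and 2 higher alveolar type 2 genes. With every library rescaled to the same total, 16 of 16 club cell, 13 of 13 endothelial and 13 of 14 alveolar type 2 genes were lower adjusted over the list alone. With that scaling the medians of the alveolar type 2 and cholesterol lists turned negative (−1.21 and −1.32), against a median gene at −1.45.

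All 3 naphthalene libraries carried the high read share and no control library did, and with that share as a term, which rests on osimertinib 2 alone, 1 of the 6 calls, smooth muscle (−0.73), was left. The other medians there were −0.32 for club cell (adjusted p = 0.752), 0.13 for alveolar type 2 (0.791), −0.16 for endothelial (0.447) and −0.35 for immediate early (0.281), and the cholesterol median turned to −0.17 (0.752). Single libraries mattered. The club cell call was lost without control 1 (median −0.26, adjusted p = 0.113), and without naphthalene 1 or 3 at nearly the same medians (−0.41 and −0.40, adjusted p = 0.0913 and 0.304). The smooth muscle call was lost without control 2 (−0.39, adjusted p = 0.0518), control 3 (−0.25, 0.225), naphthalene 1 (−0.47, 0.0720) or naphthalene 3 (−0.26, 0.376), and its median was −0.61 without control 1. The endothelial call was lost without control 3 (−0.15, adjusted p = 0.0604), naphthalene 1 (−0.19, 0.168) or naphthalene 3 (−0.21, 0.0915). The cholesterol call was lost without control 1 (0.08, adjusted p = 0.0667) or naphthalene 1 (0.0077, 0.311), and its median was 0.31 without control 2. With array weights the club cell call was lost (−0.38, adjusted p = 0.0527), without naphthalene 3 and osimertinib 3 together the club cell (−0.40, adjusted p = 0.238) and smooth muscle (−0.26, 0.411) calls, and with equal totals the cholesterol call (adjusted p = 0.976). The gene count became 12 without osimertinib 2, whose spread enters the shared fit, and 1 without naphthalene 3, and the list count became 3 without naphthalene 1 and 10 without osimertinib 3. By the rule for named genes the leading genes with higher values were mt-Rnr1, mt-Rnr2, mt-Atp8 and Lars2 (log2 9.63, 4.70, 1.75 and 11.24), each also high in osimertinib 2, and those with lower values beside Cldn10 were Camk2n1, Ybx3 and Endov (−0.65, −0.55 and −0.78). The naive T cell list had a median of −0.06 with the test pointing up, and neither it, the pan T cell list (−0.21), the EGFR list (−0.03) nor the ERK output list (−0.28) was called.

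Osimertinib was set against naphthalene to ask what the drug added to the injury. Genes of B cells were lower and interferon-stimulated genes higher in the osimertinib libraries (adjusted p = 0.237 and 0.239 with an estimated correlation, so neither call held there). The B cell surface protein Ms4a1 was at 13 ± 6.02 (SD, n = 5) against 35.8 ± 10.5 (SD, n = 3), and 11 of 12 B cell genes fell adjusted over the list alone. With every library rescaled to the same total 6 of the 12 lay above 0, where the median gene lay well above 0 too. Of 16 interferon-stimulated genes, 15 rose adjusted over the list alone, with the antiviral gene Oasl2 at 39.9 ± 6.12 against 18.8 ± 2.88 and the ubiquitin-like Isg15 at 10.3 ± 6.13 against 2.15 ± 1.34. Genes of naive T cells were lower (adjusted p = 0.237 with an estimated correlation): 5 of 12 fell adjusted over the list alone, among them the transcription factor Lef1 (7.81 ± 1.68 against 12.6 ± 0.75) and the interleukin 7 receptor Il7r (9.61 ± 1.69 against 14.2 ± 1.80). Both turned positive with every library rescaled to the same total (log2 0.43 and 0.56), where they stayed below the median gene. With the replicate number as a block 3 of the 12 fell, and Il7r did not pass (adjusted p = 0.0758). With limma 0 members of these lists passed over all genes tested. With DESeq2 some did, among them Oasl2 (adjusted p = 0.000345), Isg15 (0.0183) and Ms4a1 (0.0183). With the read-share term, which rests on osimertinib 2 alone, the list counts were 0 lower B cell, 2 higher interferon-stimulated and 0 lower naive T cell genes, and in osimertinib 2 alone against naphthalene, its spread assumed and not measured, 8, 1 and 0. Without naphthalene 2 the interferon-stimulated count was 4. The naive T cell count was 3 without naphthalene 1 or osimertinib 5 and with the 2 groups alone, 2 without naphthalene 2 or naphthalene 3, and 0 with array weights. With every library rescaled to the same total 0 B cell genes passed, and 6 naive T cell genes were higher and 0 lower. These counts follow the median gene, which lay well above 0 there. By camera the B cell list was still called lower with that scaling (adjusted p = 1.03e-21). The naive T cell test still pointed down, without a call (adjusted p = 0.176). Cd4 itself was at 2.45 ± 0.722 against 2.59 ± 1.89. No direction is given for it, since the difference of its mean log2 values was 0.04 (SE 0.31), opposite in sign to that of its means.

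Genes of monocyte-derived macrophages and of the extracellular matrix were higher (adjusted p = 0.237 and 0.305 with an estimated correlation). Of 14 genes of monocyte-derived macrophages 9 rose adjusted over the list alone, among them Trem2, a lipid receptor (3.50 ± 1.43 against 1.18 ± 0.718) and the lipoprotein gene Apoe (205 ± 15.1 against 158 ± 21.8). Of 17 genes of the extracellular matrix list 4 rose adjusted over the list alone: the collagens Col3a1 (506 ± 70.3 against 313 ± 48.8) and Col5a2, elastin (Eln, 229 ± 31.5 against 107 ± 38.1) and Lox, which cross-links both. Of the glucocorticoid targets 1 of 12 rose adjusted over the list alone, the cell cycle inhibitor Cdkn1a (42.5 ± 8.93 against 23.4 ± 2.65). Cdkn1a was also the 1 gene to rise in the p53 target and injury-associated epithelial lists, neither of which was called. Of the club cell genes 1 of 16 fell adjusted over the list alone, the paraoxonase Pon1 (10.7 ± 3.86 against 23.8 ± 5.98, and log2 0.0077 with every library rescaled to the same total). With the replicate number as a block the glucocorticoid and club cell counts were 5 and 2. The macrophage count was 1 without naphthalene 1, 4 without naphthalene 2 and with the 2 groups alone, 5 with array weights and without naphthalene 3 and osimertinib 3 together, 0 with the read-share term and 1 in osimertinib 2 alone. The matrix count was 7 without osimertinib 3, 10 without osimertinib 2 and 3 together, 2 with quantile normalisation and in osimertinib 2 alone, and 16 with equal totals. The glucocorticoid count was 2 without naphthalene 1 or osimertinib 2, 4 without osimertinib 3, 5 without osimertinib 4 or without osimertinib 2 and 3 together, 6 without naphthalene 3 and osimertinib 3 together, and 12 with equal totals. It was 0 with array weights, with the read-share term and in osimertinib 2 alone. The club cell count was 3 without naphthalene 3 and osimertinib 3 together, and 0 with array weights and the read-share term, while with equal totals 9 club cell genes were higher and 0 lower. Counts with equal totals follow the median gene, which lay well above 0 there. By camera the club cell list was still called lower with that scaling (adjusted p = 0.00257).

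In all, 15 of 39 lists were called, and none of these calls held with an estimated correlation (adjusted p = 0.237 to 0.635). Higher were the interferon-stimulated (median log2 0.88, adjusted p = 0.239 with an estimated correlation), monocyte-derived macrophage (0.63, 0.237), glucocorticoid target (0.60, 0.237), cardiac muscle (0.57, 0.635), dendritic cell (0.52, 0.237), mitotic (0.43, 0.635) and extracellular matrix (0.34, 0.305) lists. Lower were the B cell (median log2 −1.07, adjusted p = 0.237 with an estimated correlation), mitochondrial transcript (−0.52, 0.305), club cell (−0.40, 0.305), cytotoxic lymphocyte and NK (−0.31, 0.354), naive T cell (−0.27, 0.237), pan T cell (−0.15, 0.305), cholesterol (−0.15, 0.575) and alveolar type 1 (−0.11, 0.534) lists. The mitochondrial list had a mean of 0.47 against its negative median and test. Its members went opposite ways, with 3 above 0 and 6 below. Examples are mt-Atp6 (1111 ± 756 against 137 ± 41.7) and mt-Nd2 (665 ± 112 against 1028 ± 118). Another member, mt-Co2, was above 0 in osimertinib 2 alone among these libraries, so the mean rests partly on 1 library. For the dendritic, cardiac, mitotic, cytotoxic, pan T, cholesterol and alveolar type 1 lists 0 members passed adjusted over the list alone, and with the replicate number as a block 3 cytotoxic and 2 alveolar type 1 members did. Without 1 library some of these counts were above 0: 2 cytotoxic genes were lower without osimertinib 4, 3 dendritic genes were higher and 1 lower without naphthalene 2, 2 dendritic genes were higher without osimertinib 1, 2 cardiac genes without osimertinib 3, 1 cardiac gene without naphthalene 2 and 1 mitotic gene without naphthalene 1. With every library rescaled to the same total, the club, naive T, pan T, cytotoxic, alveolar type 1, cholesterol and mitochondrial medians turned positive (0.77, 0.87, 0.70, 0.48, 1.08, 1.01 and 0.66), against a median gene at 1.10, and the B cell median was 0.00. The EGFR list (0.16) and the ERK output list (0.18) were not called, and Egfr was at 39.1 ± 9.05 against 44.4 ± 4.82.

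By fry 5 lists passed, the B cell, interferon-stimulated, monocyte-derived macrophage, dendritic and glucocorticoid lists (adjusted p = 0.0454). With the replicate number as a block, the cardiac call was lost (0.38, adjusted p = 0.219). The block added calls of the alveolar type 2 (0.21, adjusted p = 0.0424), injury-associated epithelial (0.26, 0.0398), alveolar macrophage (0.41, 0.00105), adipocyte (−1.12, 0.0424) and erythroid (0.98, 0.00710) lists. The blocked contrast rests on osimertinib 1 to 3, since numbers 4 and 5 have no naphthalene library. Among the osimertinib libraries, osimertinib 3 had the highest mean of each of these lists except adipocyte, where it had the lowest.

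Osimertinib 2 alone shared the high read share of the naphthalene libraries. It was set against them as a group of 1 library, whose spread was not measured but assumed to be that of the naphthalene libraries. On that assumption the B cell (−0.87), interferon-stimulated (0.82), club cell (−0.44) and extracellular matrix (0.31) lists were called, and the dendritic (0.29), mitotic (0.18), cholesterol (0.07, turned positive) and mitochondrial (−0.17) lists were not. The alveolar type 1 (−0.25), pan T (−0.36), cytotoxic (−0.67) and glucocorticoid (0.36) medians moved by over 1.5 times and were called there. With the read-share term the medians were the same, since that term rests on osimertinib 2, and 7 of the 15 calls were lost. These were the naive T (−0.27, adjusted p = 0.0750), glucocorticoid (0.36, 0.0509), cardiac (0.45, 0.0530), dendritic (0.29, 0.170), mitotic (0.18, 0.772), cholesterol (0.07, 0.826) and mitochondrial (−0.17, 0.900) calls. Single libraries ended other calls. Without naphthalene 3 the cytotoxic (−0.23, adjusted p = 0.0517), dendritic (0.41, 0.144), mitotic (0.39, 0.141), cardiac (0.21, 0.873) and mitochondrial (−0.43, 0.0517) calls were lost, and the extracellular matrix and cholesterol medians were 0.19 and −0.32. The alveolar type 1 call was lost there too (adjusted p = 0.382), and its median turned to 0.06 while its test still pointed down. Without naphthalene 2 the club cell (−0.12, adjusted p = 0.159) and mitochondrial (−0.44, 0.0506) calls were lost, and the alveolar type 1, pan T and cardiac medians were −0.19, −0.24 and 0.87. Without naphthalene 1 the cholesterol call was lost (−0.0065, adjusted p = 0.440), and the club cell, pan T and cytotoxic medians were −0.24, −0.25 and −0.53. Without osimertinib 3 the mitotic call was lost (0.18, adjusted p = 0.348) and the club cell median was −0.19. The cardiac call was lost without osimertinib 1, 2, 4 or 5 (0.40, 0.51, 0.48 and 0.48, adjusted p = 0.0596 to 0.114). The cholesterol median was −0.08 without osimertinib 1, and the alveolar type 1 and pan T medians were −0.16 and −0.08 without osimertinib 5.

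Other settings ended some of the same calls. With quantile normalisation the club cell (−0.33, adjusted p = 0.0810) and mitochondrial (−0.30, 0.578) calls were lost, and without osimertinib 2 and 3 together the club cell (−0.08, 0.166) and mitotic (0.13, 0.377) calls. With array weights the cytotoxic (−0.13, adjusted p = 0.0767), dendritic (0.36, 0.0885) and mitotic (0.13, 0.487) calls were lost, and with a mean of 5 CPM the mitotic (0.48, 0.110) and cardiac (0.59, 0.122) calls. Without naphthalene 3 and osimertinib 3 together the alveolar type 1 (0.013, adjusted p = 0.413), cytotoxic (−0.14, 0.0951), dendritic (0.31, 0.268), mitotic (0.18, 0.825) and cardiac (0.36, 0.297) calls were lost. With equal totals the alveolar type 1 (adjusted p = 0.446), naive T (0.176), dendritic (0.166), mitotic (0.158), cholesterol (0.740), cardiac (0.159) and mitochondrial (0.0611) calls were lost.

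No single gene passed: limma called 0 of 16225, with 1671 at an unadjusted p under 0.05 (1148 higher, 523 lower), edgeR called 0 and DESeq2 33. The smallest adjusted p was that of Oasl2, at 0.105 (log2 1.05, SE 0.14), and it ran from 0.000345 to 1.00 over the alternatives. The other leading genes by rule were Hmgn2, Camk2n1 and Gbp6 with higher values (log2 0.68, 0.54 and 1.06), and Siglecg, an inhibitory receptor of B cells, Cacna1i, mt-Atp8 and Btla, an inhibitory receptor of lymphocytes, with lower values (−1.22, −1.44, −1.41 and −1.06). Groups did not overlap in 963 genes (5.94%), where chance gives 3.57%. The count became 11 without osimertinib 2, 4 without osimertinib 3, and 1 without control 1, naphthalene 3 or osimertinib 1.

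**Figure D2:**
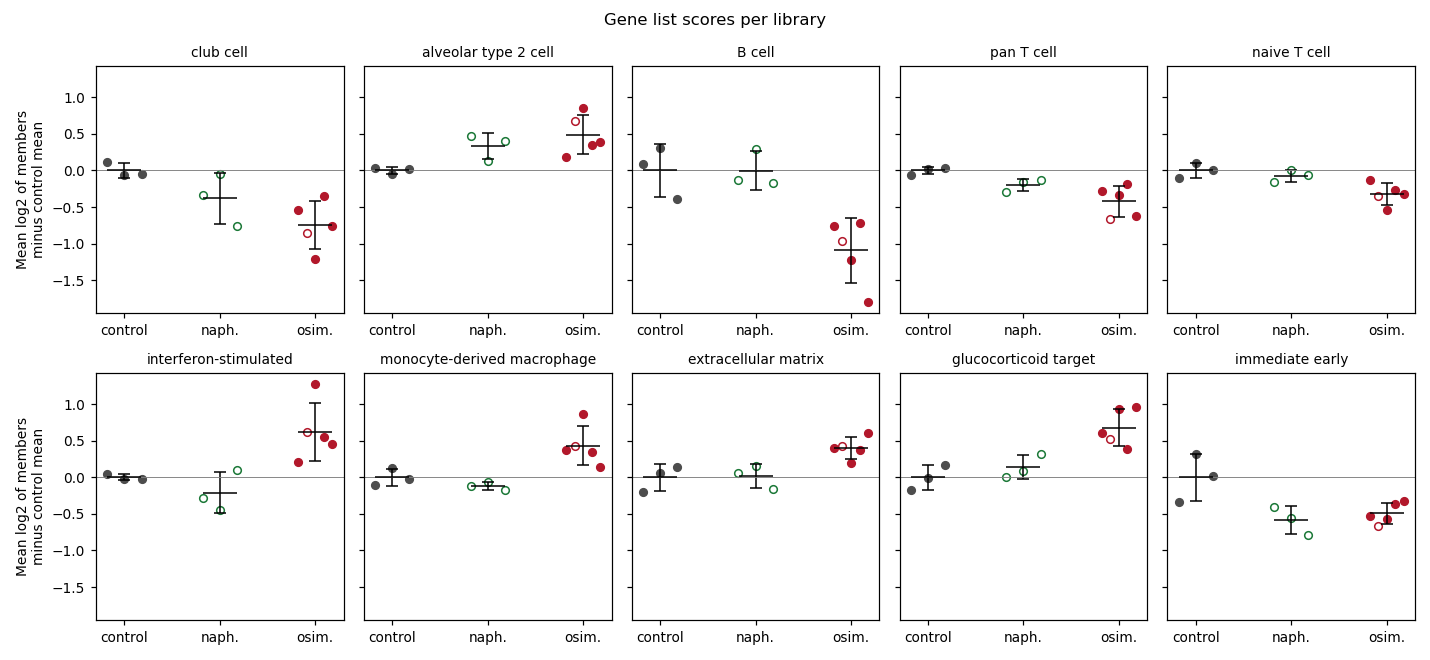
Mean log2 value of the measured members of 10 gene lists in each library, less the control mean, by group. Points are libraries, open where the unnamed gene takes over 10% of the reads, horizontal bars are group means and error bars are SDs. The B cell points of the osimertinib libraries lie below those of the control and naphthalene libraries.

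Osimertinib was set against control to ask how the lung after both agents differed from the untreated lung. Mmp2, a matrix metalloproteinase that cleaves gelatin and type IV collagen, rose to 74.8 ± 7.11 (SD, n = 5) from 35.4 ± 0.243 (SD, n = 3), a log2 change of 1.05 (SE 0.11, adjusted p = 0.0113), higher in 5 of 5 libraries than in every control. The control SD was below the counting error at this level, where 1 read was worth 0.0568 to 0.0668, so it understates the spread. Mmp2 was the only gene of 16225 to pass. Club cell genes were lower (adjusted p = 0.0522 with an estimated correlation), with Scgb1a1 at 4671 ± 2224 against 11111 ± 1306 and Cyp2f2 at 651 ± 263 against 1299 ± 156, and 6 of 16 fell adjusted over the list alone. B cell genes were lower (adjusted p = 0.0765 with an estimated correlation), with Ms4a1 at 13 ± 6.02 against 34.1 ± 7.36, and 11 of 12 fell adjusted over the list alone. Matrix genes were higher (adjusted p = 0.0765 with an estimated correlation), with the collagen Col3a1 at 506 ± 70.3 against 261 ± 16.5, and 7 of 17 rose adjusted over the list alone, among them Col5a2, Lox and Eln. With limma none of these list members passed over all genes tested. With DESeq2 some did, among them Col3a1 (adjusted p = 4.01e-07), Col5a2 (0.000147), Pon1 (0.000829) and Ms4a1 (0.0218). The club cell count was 2 without control 1, control 2, control 3 or osimertinib 2, without osimertinib 2 and 3 together and with the read-share term. It was 10 with array weights, 11 with equal totals and 13 without naphthalene 3 and osimertinib 3 together. The matrix count was 3 without control 1, 4 without control 2, control 3, naphthalene 2, osimertinib 2, osimertinib 4 or osimertinib 5 and with the read-share term, and 0 with equal totals. With equal totals the median gene lay below 0, and camera still called the matrix list higher (adjusted p = 5.29e-09).

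The pan T cell and naive T cell lists were lower in the osimertinib libraries, calls that did not hold with an estimated correlation (adjusted p = 0.0778 and 0.0801). All 15 pan T cell genes lay below control (median log2 −0.46), with the signalling kinase Lck at 5.44 ± 0.659 against 8.17 ± 1.06 and the receptor chain Cd3e at 3.52 ± 1.04 against 5.59 ± 0.49, though 0 passed adjusted over the list alone. Of 12 naive T cell genes 4 fell adjusted over the list alone, among them the transcription factors Satb1 (18.2 ± 6.70 against 34.5 ± 3.69) and Tcf7 (14.2 ± 2.37 against 21.7 ± 4.71) and the homing receptor Ccr7 (8.16 ± 1.34 against 12.1 ± 1.82). Cd8a, which marks cytotoxic T cells, was the 1 of 13 cytotoxic and NK genes that fell adjusted over the list alone (2.20 ± 0.555 against 4.56 ± 0.833). Cd4 was at 2.45 ± 0.722 against 3.43 ± 1.31, a log2 difference of −0.35 (SE 0.31) that passed no test. The pan T cell count was 3 without osimertinib 4 and without a variance trend, 4 without naphthalene 3 and osimertinib 3 together, 7 with array weights, 8 with equal totals and 6 over control 1 to 3 and osimertinib 1, 4 and 5. The naive T cell count was 1 without control 1 or control 3 and 0 without control 2 or osimertinib 5. The cytotoxic count was 0 without control 2, control 3, osimertinib 2 or osimertinib 5, without osimertinib 2 and 3 together and with the read-share term, 5 without osimertinib 4 and 11 with equal totals.

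Of 14 alveolar type 2 genes 7 rose adjusted over the list alone, for example the surfactant protein Sftpd (447 ± 128 against 266 ± 30.2) and the complement gene Hc (1106 ± 237 against 628 ± 56.0). Of 14 alveolar macrophage genes 5 rose adjusted over the list alone, for example the integrin Itgax (55.1 ± 8.42 against 35.4 ± 1.10) and Chil3 (503 ± 160 against 278 ± 18.1). Of 14 monocyte-derived macrophage genes 7 rose, for example Spp1 (48.0 ± 8.72 against 30.1 ± 5.68), and of 16 interferon-stimulated genes 9 rose, for example Ifi44 (14.4 ± 2.16 against 7.0 ± 0.821) and Oasl2 (39.9 ± 6.12 against 25.2 ± 1.65), both counts adjusted over the list alone. Of 12 glucocorticoid targets 7 rose adjusted over the list alone, among them the metallothionein genes Mt1 (36.8 ± 26.2 against 15.3 ± 2.78) and Mt2, Lcn2 and Cdkn1a, the last of which also rose in the p53 list adjusted over the list alone. The acute-phase gene Saa3 rose and the immediate early genes Nr4a1 (22.6 ± 4.13 against 69.6 ± 25.8) and Egr1 (18.6 ± 11.1 against 66.9 ± 28.2) fell, adjusted over their lists alone. Osimertinib 3 held the highest osimertinib values of Mt1, Mt2, Isg15, Sftpc and Areg.

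These counts depended on the control libraries and on the scaling. With every library rescaled to the same total 0 alveolar type 2 (median log2 0.11), 0 monocyte-derived macrophage (0.19), 0 interferon-stimulated (0.29) and 1 glucocorticoid (0.25) genes were higher, and 0 alveolar macrophage genes were higher and 1 lower (0.10). The median gene lay below 0 there, and camera still called each of these lists higher. The 7 alveolar type 2 genes became 0 without control 2, 3 without control 1, with quantile normalisation or without osimertinib 2 and 3 together, and 4 without control 3 or osimertinib 2 and with the read-share term. The 5 alveolar macrophage genes became 0 without control 2. The 7 monocyte-derived macrophage genes became 0 without control 1, control 3 or osimertinib 2 and 3 together, and 2 without osimertinib 4. The 9 interferon-stimulated genes became 4, 2 and 3 without control 1, 2 and 3. The 7 glucocorticoid targets became 0 without control 1, control 2, naphthalene 1, naphthalene 2, naphthalene 3 or osimertinib 2, 1 without control 3, and 4 without osimertinib 1 or osimertinib 5. They also became 0 with a pseudocount of 5, a mean of 5 CPM, the 2 groups alone, no variance trend and the read-share term. The 1 p53 gene became 0 without each library except control 3 and osimertinib 4, and with equal totals. The 2 immediate early genes became 1 without control 2, 4 without control 1 or osimertinib 4 and with equal totals, and 5 with array weights. The 1 cytokine gene became 2 without naphthalene 3 or osimertinib 1 and with array weights.

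In all, 17 of 39 lists were called, and 1 of these calls held with an estimated correlation, that of the glucocorticoid targets (adjusted p = 0.0421, and 0.0522 to 0.239 for the others). Lower were the B cell (median log2 −1.06, adjusted p = 0.0765 with an estimated correlation), club cell (−0.79, 0.0522), cytotoxic lymphocyte and NK (−0.49, 0.0928), pan T cell (−0.46, 0.0778), smooth muscle (−0.43, 0.239), naive T cell (−0.26, 0.0801) and immediate early (−0.25, 0.0801) lists. Higher were the interferon-stimulated (median log2 0.63, adjusted p = 0.0801 with an estimated correlation), glucocorticoid target (0.61, 0.0421), monocyte-derived macrophage (0.51, 0.0801), alveolar type 2 (0.49, 0.0801), inflammatory cytokine (0.49, 0.132), alveolar macrophage (0.45, 0.171), dendritic cell (0.35, 0.0928), extracellular matrix (0.34, 0.0765), injury-associated epithelial (0.18, 0.239) and p53 target (0.15, 0.0765) lists. With every library rescaled to the same total, the medians of the extracellular matrix, injury-associated and p53 lists turned negative (−0.01, −0.18 and −0.22), against a median gene at −0.34. For the smooth muscle, dendritic and injury-associated lists 0 members passed adjusted over the list alone, though 3 smooth muscle genes were lower without control 1 (5 with array weights or equal totals), 1 dendritic gene was higher without naphthalene 1 or osimertinib 1, and 1 to 3 injury-associated genes were higher without control 3, osimertinib 1, osimertinib 3, osimertinib 4 or osimertinib 5. The EGFR list (0.02, 8 members measured) and the ERK output list (−0.09, 13 members measured) were not called, although Egr1, a member of the latter, fell adjusted over that list alone, and Egfr was at 39.1 ± 9.05 against 37.3 ± 3.00.

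By fry 3 lists passed, glucocorticoid targets, club cell and B cell (adjusted p = 0.0464). Over control 1 to 3 and osimertinib 1, 4 and 5, the 6 libraries left without the high read share and osimertinib 3, the B cell list was at −1.12 with 12 of 12 lower, the club cell list at −0.58 with 12 of 16 lower and the extracellular matrix list at 0.45 with 13 of 17 higher, adjusted over each list alone. There the injury-associated (0.08, adjusted p = 0.314) and inflammatory cytokine (0.13, adjusted p = 0.0513) calls were lost. Called but smaller by over 1.5 times there were the cytotoxic (−0.32), naive T (−0.15), monocyte-derived macrophage (0.31), alveolar type 2 (0.29), alveolar macrophage (0.23) and dendritic (0.14) medians. Without osimertinib 3 alone the injury-associated call was lost (0.13, adjusted p = 0.0946), and the monocyte-derived macrophage, alveolar macrophage, cytokine and smooth muscle medians were 0.33, 0.26, 0.23 and −0.28. The dendritic call was lost without control 1 (0.33, adjusted p = 0.117), where the extracellular matrix, smooth muscle and immediate early medians were 0.20, −0.65 and −0.41. The immediate early median was −0.14 without control 2, the smooth muscle median −0.27 without control 3, and the dendritic and p53 medians 0.23 and 0.22 without osimertinib 1. The injury-associated call was also lost with array weights (0.12, adjusted p = 0.101), without naphthalene 3 and osimertinib 3 together (0.13, 0.141) and without osimertinib 2 and 3 together (0.08, 0.137), and the dendritic call with array weights (0.20, 0.0681) and without naphthalene 3 and osimertinib 3 together (0.25, 0.0532).

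Mmp2 was called in 20 of 27 alternatives, with log2 changes of 0.98 to 1.10 and adjusted p from 7.39e-18 to 0.157. The 7 losses were without control 1, 2 or 3 (adjusted p = 0.134, 0.145 and 0.157), without osimertinib 1 (0.0642) or osimertinib 5 (0.0617), without a variance trend (log2 1.05, adjusted p = 0.0687) and with the replicate number as a block (log2 1.08, adjusted p = 0.135). With equal totals, which are not among the 27, the call was lost too (log2 0.69, adjusted p = 0.608). Besides Mmp2, limma found 779 genes at an unadjusted p under 0.05 (374 higher, 405 lower), edgeR called 1 gene and DESeq2 78, and the count became 2 without osimertinib 2 or without osimertinib 3. Groups did not overlap in 1028 genes (6.34%), where chance gives 3.57%. The other leading genes by rule were Col3a1, Col5a2 and Ctsk, a collagen-degrading cathepsin, with higher values (log2 0.94, 0.65 and 1.08), and Nr4a1, Pon1 and Cacna1i with lower values (−1.53, −1.45 and −1.30). Col3a1 passed in the 6 libraries named above (log2 1.03, adjusted p = 0.0192) and in 5 of 27 alternatives in all, with adjusted p from 4.01e-07 to 0.919.

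**Figure D3:**
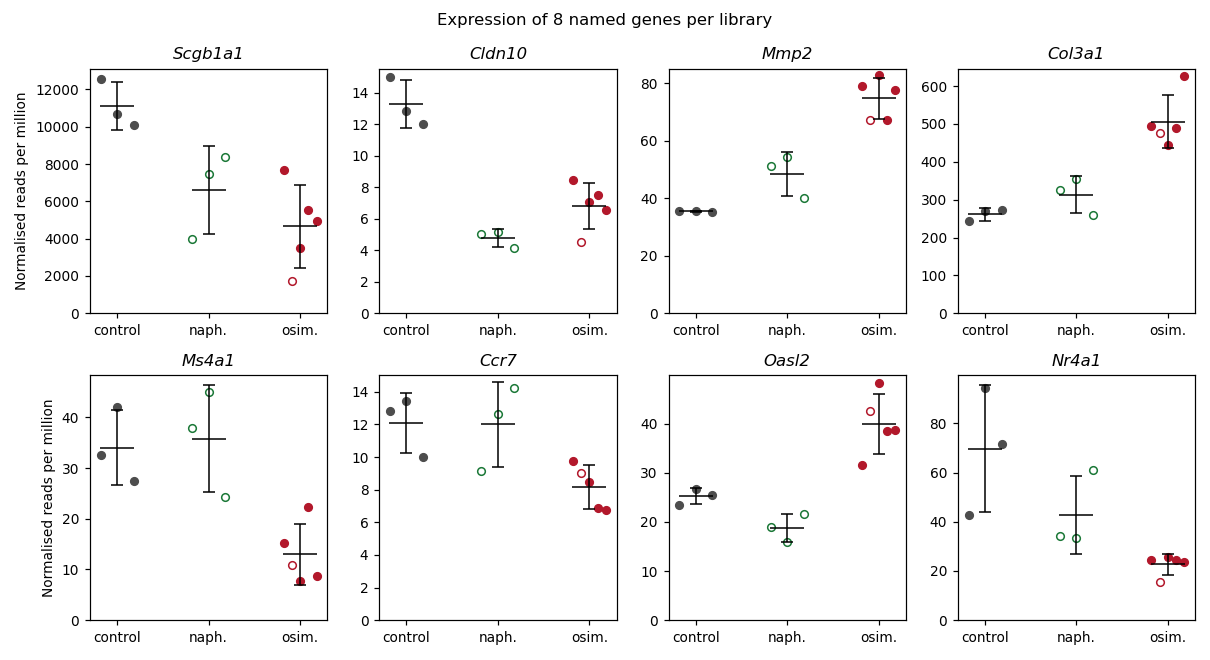
Deposited values of 8 genes in each library by group, in CPM of normalised library size on a linear axis from 0. Points are libraries, open where the unnamed gene takes over 10% of the reads, horizontal bars are group means and error bars are SDs. Mmp2 lies at 74.8 ± 7.11 in the osimertinib group and 35.4 ± 0.243 in control.

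No gene was called in more than 1 comparison. Across the 16225 genes, which are not independent replicates, the log2 differences of naphthalene against control and of osimertinib against control had r = 0.396, where unchanged groups sharing the control libraries gave 0.557 over 100 simulations, and a covariance of 0.0308 beside a simulated 0.0392. For naphthalene against control and osimertinib against naphthalene, which share the naphthalene libraries with opposite sign, r was −0.742 beside −0.561 and the covariance −0.0792 beside −0.0396. For the comparisons that share the osimertinib libraries r was 0.322 beside 0.375 and the covariance 0.0243 beside 0.0237. The control libraries were too few to split, so part of any excess may come from the shared libraries. The simulated values are close to those of libraries with equal spread. The spread here was unequal, with array weights from 0.154 (osimertinib 3) to 3.04 (control 2). The simulations therefore cannot tell whether any of these r values lies above or below that of sharing alone.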

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

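The tests of ribosomal RNA removal and of a naphthalene response, and those of library quality and of lymphoid tissue for the B cell genes, were chosen only after the result was seen, as were the settings that leave out or adjust for named libraries. Among the 5 osimertinib libraries, 210 values were tested for a library far from the others (gap over range above 0.710), and 23 (11%) passed, where chance gives about 1 in 20. Of these, 17 were osimertinib 3, 5 osimertinib 2 and 1 osimertinib 5.

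In osimertinib 2, ENSMUSG00000119584 took 43.9% of the reads against at most 0.0337% in the other 4 (gap over range 1.00), mt-Rnr1 was at 26723 against at most 314 (0.990), Lars2 at 45982 against at most 35.2 (1.00) and mt-Atp8 at 71.5 against at most 33.5 (0.840). Naphthalene 1 to 3 held the same high read share. A response to naphthalene, which all 5 osimertinib mice also had, would leave the osimertinib libraries together, and the share in osimertinib 2 exceeded the next by 1300 times, which argues against it. Less complete removal of ribosomal RNA in these 4 libraries may be a source: mt-Rnr1 set against mt-Nd1 was at least 74.7 times higher in each of them than in each of the other 7, and mt-Rnr2 at least 2.22 times. The labels give no batch, and all 3 naphthalene libraries are among the 4, so this share and naphthalene itself are largely confounded in comparisons with that group. Nr4a1 was lowest in osimertinib 2 (15.4 against at least 23.7, gap over range 0.826).

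Osimertinib 3 had a first principal component score of −72.7 against 3.07 to 14 in the other 4 (0.874). It had a share of 16.7% for the pair recorded under ENSMUSG00000118841 against at most 3.20% (0.893). Naphthalene 3, at −26.2, lay on the same side. Transcript length accounted for 15.3% and GC content for 2.79% of the variance across genes of the deviation of osimertinib 3 from the control mean, which argues against either as the whole source, with values for 99.6% of kept genes. Length still took a larger part in osimertinib 3 than in any other library (at most 3.82%, in naphthalene 3). Short transcripts were higher there (Spearman correlation with length −0.383), so a part of the deviation goes with length. Mitochondrial ribosomal RNA was also high in osimertinib 3 for a library without the high read share. There mt-Rnr1 and mt-Rnr2 set against mt-Nd1 were at 0.295 and 15.6. The other such libraries had at most 0.0774 (osimertinib 5) and 3.79 (osimertinib 1). Naphthalene 3 had the highest values of all libraries (63.0 and 107). Whether this goes with the deviation was not tested. A difference in tissue taken or in RNA quality other than length was not tested, and no biological explanation was tested. Osimertinib 3 also stood apart in the mean of the injury-associated epithelial list (0.909 above control against at most 0.237, gap over range 0.811) and, at the low end, of the cardiac muscle list (−0.588 against at least 0.162, gap over range 0.745).

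Among single genes, osimertinib 3 was highest in Sftpc at 17256 (gap over range 0.782), Areg at 12.5 (0.831), Isg15 at 21.1 (0.851), Kif11 at 10.6 (0.813), Cdk1 at 10.7 (0.877) and Kif20a at 10.7 (0.810). It was also highest in Sgk1 at 117 (0.861), Itgae at 10.7 (0.890), Osm at 3.74 (0.724), Il1a at 7.48 (0.768), Mt2 at 39.7 (0.760), Mt1 at 83.2 (0.859) and Ccl21a at 114 (0.868). Osimertinib 5 was highest in Col3a1 at 627 against at most 495 (0.726).

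The B cell list was lower in osimertinib than in control (adjusted p = 0.0765 with an estimated correlation), and an effect of osimertinib, of naphthalene or of both on B cells is the biological explanation the design names. In naphthalene against control the B cell median was 0.04, with 9 of 12 members above 0 and no call. In osimertinib against naphthalene it was −1.07, with 12 of 12 below 0. These values argue against naphthalene alone, as far as naphthalene libraries with the high read share can tell. The labels give no time, so a later effect of naphthalene alone stays open. An effect of osimertinib, alone or with naphthalene, stays untested. Library quality is argued against, since without the 4 high-share libraries and osimertinib 3 the median was −1.12, which is 1.06 times that over all libraries, and so is the authors' scaling, since the smaller of the rescaled medians was 0.974 times the deposited one. Less lymphoid tissue taken along with the lung could also lower these genes: the stromal chemokine genes Ccl19, Ccl21a and Cxcl13 had a median log2 of 0.30, and Ccl19 (0.30, SE 0.29) and Ccl21a (0.85, SE 0.30, with osimertinib 3 at 114 against at most 46.3 in the other 4) lay well above the B cell median of −1.06. Ccl21a has near-identical copies that can share its reads. This stays open because Cxcl13 (−0.71, SE 0.84) was too variable to decide.

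Chance was weighed by regrouping the libraries of each comparison. For osimertinib against control, 3 of 56 splits called at least as many genes as the real 1 (highest other 1) and 15 of 56 at least as many lists as the real 17 (highest other 23), so chance was not excluded for either count. For osimertinib against naphthalene, 6 of 56 splits called at least the real 15 lists (highest other 19), so chance was not excluded for that count. No gene was called, and all 56 of 56 splits reach a count of 0 (highest other 70), so the splits decide nothing on genes there. The split that called 70 genes set naphthalene 3, osimertinib 3 and osimertinib 5 against the other libraries, which points to the structure of naphthalene 3 and osimertinib 3, and it parted 0 of the 3 same-number pairs. Of the 8 splits that part all 3 pairs, as the real one does, the real one called the most lists (15, highest other 14), and 8 splits are too few. The other 5 splits with at least 15 lists parted fewer pairs. For naphthalene against control the 10 splits were too few: a count of 0 genes is reached by all 10 of 10 (highest other 0), and 9 of 10 called at least the real 6 lists (highest other 10).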

How the results depend on the processing

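The settings that leave out osimertinib 2 and 3, or naphthalene 3 and osimertinib 3, together, the read-share term (estimated from osimertinib 2 against the other osimertinib libraries alone), the 6 even libraries (control 1 to 3, osimertinib 1, 4 and 5) and the 4 high-share libraries were chosen after seeing the data. Genes changed, given for naphthalene against control, osimertinib against naphthalene and osimertinib against control in turn (0, 0 and 1 as reported), were 15763, 14420 and 96 with equal totals, 5, 4 and 149 with array weights, 12, 33 and 78 with DESeq2, 2, 2 and 2 with the read-share term, 202, 189 and 3 without naphthalene 3 and osimertinib 3, and 38, 47 and 2 without osimertinib 2 and 3. With the groups compared alone the first count was 21 and the second 1, with quantile normalisation the second was 1, in the 6 even libraries the third was 3, and without a variance trend or with the replicate block it was 0. Leaving out 1 library gave 0 to 12, 0 to 11 and 0 to 2 genes. With equal totals the shift of the median gene shows the cause; for the others the cause was not tested. Lists called (6, 15 and 17) were 0, 0 and 1 with an estimated correlation and 0, 5 and 3 with fry, and the first count was 13 with its groups alone, 10 with the replicate block and 1 with the read-share term. Leaving out 1 library gave 3 to 10, 11 to 17 and 16 to 20 lists. Genes called in both comparisons with control (0) were 89 with equal totals, 3 with DESeq2, 1 with the read-share term and in both settings without a pair of libraries, and 0 to 1 leaving out 1 library. The block gave 0, 0 and 0 genes and 10, 19 and 20 lists, and its contrasts with osimertinib rest on osimertinib 1 to 3. In osimertinib against naphthalene, where the numbers were taken to pair the libraries, it changed no other call of a list, or of a gene over all genes, than those given with the results. Same-number correlations were −0.09 to 0.20 between control and naphthalene (1 of 3 over 0.1) and −0.15 to 0.07 between control and osimertinib (0 of 3), where 2 of 6 and 1 of 6 libraries correlated best with their own number, so there the numbers were not taken to pair the libraries. In osimertinib against control the block gave 10 lower club cell, 7 cytotoxic, 4 immediate early and 2 naive T cell genes adjusted over the list alone, and 3 higher and 1 lower injury-associated genes.

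Results that reversed did so mostly with equal totals. In naphthalene against control these were the mitochondrial list (−1.10), Lamp3 (−0.87), Chil1 (−1.02), Slc34a2 (−1.10), Hc (−1.18), Il7r (−0.90), Lef1 (−1.16), Egfr (−1.28), Cyp51 (−1.06), Sc5d (−1.21), Msmo1 (−1.12), Idi1 (−1.29), Areg (−0.77) and Cd3e (−1.26). In osimertinib against naphthalene they were the mitochondrial list (0.66), Scgb3a1 (0.78), Pdpn (0.83), Rtkn2 (0.99), Igfbp2 (0.85), Egfr (0.95), Sc5d (0.82), Lss (0.76), Msmo1 (0.84), Sqle (0.93) and Scgb3a2 (1.14). Equal totals shift all genes together, with the median gene far below 0 in naphthalene against control and far above 0 in osimertinib against naphthalene. Set against the median gene, these single genes kept their side, except Scgb3a2. The cholesterol list reversed with the read-share term (−0.17 in naphthalene against control, 0.0685 in osimertinib against naphthalene) and in the 4 high-share libraries (0.0685). The mitotic list in osimertinib against control, not called as reported (0.09), ran from −0.20 without osimertinib 3 to 0.23 without osimertinib 1, both called, leaving out 1 library, and was called at −0.17 with array weights, −0.20 without naphthalene 3 and osimertinib 3 and −0.19 in the 6 even libraries and without osimertinib 2 and 3; the cause was not tested. Of 6546 values of named genes under alternatives, 140 differed in sign without a call on both sides. Of 3216 list values 140 lost a call and 129 gained one. The high-share libraries limit depth most, at 2018541 to 2965328 reads outside the unnamed gene.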

Other observations

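The genes in the next 2 paragraphs were chosen after their values were seen, from fixed lists that were not called, and each count is adjusted over the list alone, with 0 passing over all genes tested with limma. With DESeq2 some passed in osimertinib against control, among them Ctss (adjusted p = 0.00123), Cxcr5 (0.00429) and H2-DMb2 (0.0203). In the MHC class II presentation list, genes parted in both comparisons with osimertinib. H2-DMb2 and H2-Ob, which take part in peptide loading, fell against control (7.69 ± 1.74 against 15.8 ± 4.05, and 12.8 ± 4.55 against 25.5 ± 5.72), while the protease Ctss rose (115 ± 13.5 against 75.7 ± 2.89; SD, n = 5 and 3). Against naphthalene H2-DMb2 and H2-Ob fell too (log2 −0.97 and −0.99) and Ctss rose (0.50). Cxcr5, the chemokine receptor of B cells and follicular helper T cells, fell in both comparisons, to 4.33 ± 1.45 from 11.2 ± 2.63 in control and 10.1 ± 3.22 after naphthalene. With equal totals the differences of H2-DMb2 and H2-Ob against naphthalene turned positive (0.12 and 0.13), and that of Cxcr5 was −0.05, against a median gene at 1.10.

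Clock genes parted between osimertinib and naphthalene. Npas2 and Cry1 were higher in osimertinib (14.2 ± 1.51 against 6.63 ± 1.92, and 11.5 ± 1.20 against 6.24 ± 1.98, SD, n = 5 and 3). Nr1d1 and Dbp were lower (log2 −1.31, SE 0.43, and −1.90, SE 0.62). With the replicate number as a block none of these 4 passed (adjusted p = 0.0708 for each over the list). With array weights, and with the read-share term that rests on osimertinib 2 alone, 0 clock genes passed in either direction. With equal totals 9 were higher and 1 lower, where the median gene lay well above 0. Against control the clock list had a median of 0.0019 in osimertinib, with 7 members above 0, 7 below and 0 passing adjusted over the list alone. In naphthalene it was 0.28 against control, with 10 above 0, 4 below and no call. The differences between osimertinib and naphthalene therefore do not show a change of the list from control in the osimertinib libraries. The time of day of sampling is not given in the sources used here. Aldh3a1, an aldehyde dehydrogenase on the aryl hydrocarbon receptor list, fell in osimertinib against control (5.15 ± 2.12 against 11.7 ± 1.28). Among fibroblast genes Dpt rose (log2 0.45) and Gli1, a target of hedgehog signalling, fell (−0.62) in osimertinib against naphthalene, where with equal totals Gli1 turned positive (0.37), and with the replicate number as a block neither passed (adjusted p = 0.119 and 0.213 over the list).

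The mitochondrial gene mt-Co2 was at 8.86, 10.1 and 10.4 in control 1 to 3, listed at 0 in naphthalene 1 to 3 and in osimertinib 1, 3, 4 and 5, and at 40.0 in osimertinib 2. No fold is given, since every cell uses this gene.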
